A study of Macaca fascicularis with 24 samples.

How the data were processed

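The data were 24 libraries of single-cell RNA sequencing (10x Genomics) from cynomolgus macaque (Macaca fascicularis) embryos cultured in vitro and labelled with embryonic days E18 to E25. Each library came as a matrix of unique molecular identifiers (UMIs), a list of cell barcodes and a list of 33960 gene symbols. Per the file headers, the matrices hold UMI counts written by Cell Ranger 4.0.0, with no normalization. The submitters' notes also name Seurat 4.1.1 and the genome builds Mmul_10 and rheMac10, without their roles. The barcodes of a library had at least 500 to 610 UMIs each, so the matrices had been reduced to such barcodes before deposition. The gene list repeats the symbol as the identifier and gives no coordinates, so genes are named by symbol alone and no position is given. The extraction protocol in the labels describes sorted goblet cells of the mouse colon. It was therefore not used as a description of these samples, and how the embryos were cultured and dissociated is not known from the labels.

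Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% of UMIs from the 13 mitochondrially encoded genes. That retained 156160 of 204079 barcodes. Within each library the barcodes with the highest Scrublet doublet scores were removed, at 0.8% per 1000 barcodes, because Scrublet's automatic threshold called a median of only 3 barcodes per library. This removed 12647 barcodes and left 143513 cells, 1630 to 10489 per library, with a median of 2489 to 32571.5 UMIs per cell. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering at resolution 1 (igraph 0.11.9, seed 1) was run on the 15 nearest neighbours (scikit-learn 1.9.0, Python 3.11.15), without batch integration. Scrublet was run in scanpy 1.11.5. All steps ran on a single thread, because a run with more threads had given other clusters, which was put down to rounding.

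Clusters of at least 50 cells were named from 24 marker lists. A marker counted where its level was at least 2-fold over the median cluster, with 5 CPM (UMIs scaled to a common total) added, and at least 10% of cells held a UMI of it. At least 3 markers were needed, and among lists within 80% of the best the list with most markers among the cluster's 10 leading genes was taken. Lists of related cell types were merged. Extraembryonic mesenchyme, lateral plate mesoderm, smooth muscle or pericyte, and cardiomyocyte became mesenchyme. Erythroid, megakaryocyte and myeloid became blood. A cluster whose leading genes held more markers of another list than of its own stayed unnamed. Clusters with a median under 5000 UMIs per cell were called low-depth and clusters with at least 50% Scrublet-marked barcodes were set aside as doublets. The marker lists, cell filters, tests, gene lists and rule for named genes were fixed before the data were examined. The thresholds for naming clusters were set after the clusters' leading genes were seen, and 2 earlier rules had been tried. These thresholds were set on the clusters of an earlier run with more threads, in which the limit of 5000 UMIs fell in a wide gap; in the run reported the cluster medians beside it were 4293 and 6144, and the limit was left as it was. Class names carry the ending "-like" because they rest on transcripts alone.

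Libraries were the samples and cells were never used as replicates. UMIs were summed per library over all cells, and per library and class where a library had at least 20 cells of the class. A class was fitted when at least 12 libraries over at least 6 days entered, for the 8 largest classes that met this. The slope of log2 expression per embryonic day was tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05. All such tests were two-sided. The share of cells in each of 10 classes was related to the day by Spearman's rho and Pearson's r with two-sided permutation tests of 100000 resamples.

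There were 23 gene lists, tested with fry (limma 3.58.1) in each fit and adjusted over the lists of that fit: pluripotency, primitive streak and nascent mesoderm, HOX paralogs 1 to 4, HOX paralogs 5 to 13, collagens and matrix, hepatic-type plasma proteins, sarcomere and cardiac, embryonic erythroid, glycolysis, hypoxia response, nuclear-encoded respiratory chain, DNA replication (S phase), mitosis (G2/M phase), p53 targets, dissociation and immediate early, unfolded protein response, interferon response, retinoic acid pathway, BMP pathway, WNT pathway, FGF pathway, NOTCH pathway, and sterol synthesis. The p given for a list tests whether its genes moved, on balance, in a single direction. It does not compare the list with other genes. Named genes were, among those past an adjusted p of 0.05 with an average log2 CPM of at least 5 and neither mitochondrial nor ribosomal, the 12 with the largest rising and the 12 with the largest falling slope for whole libraries and the 8 and 8 for each class. Up to 4 members of a described list, those with the smallest p, were added, as were TBXT, SOX2, POU5F1, GATA4 and HAND1 for whole libraries. Levels are mean CPM ± SD at the first and the last day with libraries.

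Same-day libraries were compared by the division of their cells over the clusters. Those with a chi-square per degree of freedom under 3 were summed (for levels and shares, averaged), which gave 17 samples, and every test was run again on these. This alternative and its limit were chosen after the values had been seen. All n beside a mean count joined samples. The alternatives fixed in advance were DESeq2 1.42.0 size factors, its Wald test, no filter on low counts, the replicate number as a block, a depth covariate, E18 and E19 against E24 and E25, Scrublet-marked barcodes kept, a stricter cell filter (1000 genes, 2000 UMIs, 10% mitochondrial), at least 50 cells, Leiden resolutions of 0.5 and 2, each library left out in turn, and camera with an estimated correlation. Added after seeing the data were the joined samples, a second clustering seed for the classes, only cells of clusters that were not low-depth, the largest cluster of a class only, and omission of the 3 libraries with over 50% of cells in low-depth clusters.

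The whole-library test was tested on simulated data with the observed depths. Of 100 genes per size, it recovered 55% of those with a 2-fold change over the days and 76% of those with a 4-fold change, and 7 of 138 calls (5.07%) were unchanged genes. The simulated libraries were independent, without near-identical sets, so these rates do not describe the test over the 24 libraries, which hold such sets. Wilson 95% intervals were given for shares in single libraries, and for a share of 0 the limit given is 3 counts of the total, which is lower than the Wilson limit. Both cover counting error only. Blood-like cells were in too few libraries for a fit of their genes, nascent mesoderm-like cells met the minimum but were not among the 8 largest classes, and low-depth, doublet and unnamed clusters had no fit of their own.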

Results

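Single-cell transcriptomes were measured in cynomolgus macaque embryos cultured in vitro, from embryonic day E18 to E25. E18 and E23 had 4 libraries each, E19, E22, E24 and E25 had 3, and E20 and E21 had 2. The series is a time course without a control arm, and the comparisons below ask which cell classes and which genes rose or fell with the embryonic day. The total UMI count was 161578248, 63506822, 52910829 and 58554691 in E18 replicates 1 to 4, 127977951, 65411601 and 135085521 at E19, 155150810 and 97993870 at E20, and 76474042 and 135425224 at E21. It was 95761106, 88499611 and 87375979 at E22, 135237244, 130613617, 146478072 and 130520252 at E23, 175581477, 113809558 and 96399885 at E24, and 104787772, 98480021 and 102662432 at E25. The median per cell used ranged from 2489 UMIs in E18 replicate 4 to 32571.5 UMIs in E21 replicate 1.

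The 143513 cells used comprised 40526 mesenchyme-like cells (collagen, POSTN and HAND1 transcripts), 25456 trophoblast-like cells (GATA3, KRT7, VGLL1, CGA), 10375 amnion-like cells (ISL1, GABRP, VTCN1) and 2246 epiblast-like cells (POU5F1, NANOG, DPPA4). Not every cluster of a class was named on all of these markers. HAND1 did not count in mesenchyme clusters 0, 5 and 10, and clusters 18 and 21 were named on lateral plate mesoderm markers. GATA3 and CGA did not count in trophoblast cluster 6. Smaller classes were 2174 endothelium-like (PECAM1, CDH5, KDR), 1802 gut endoderm-like, 1374 blood-like, 1359 primordial germ cell-like (NANOS3, SOX17, TFAP2C), 1210 visceral or yolk-sac endoderm-like (AFP, APOA1, TTR) and 1171 nascent mesoderm-like cells (MESP1, LHX1, EOMES). A further 51010 cells (35.5%) lay in 17 low-depth clusters, with a median of 2364 UMIs per cell against 18869 in mesenchyme-like cells. Their mean share per day lay between 12.9% ± 6.03 (SD, n = 2) at E19 and 50.2% ± 24.3 (SD, n = 2) at E20. No cell annotation came with the matrices.

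Some classes depended on the clustering itself. When it was repeated with a second seed, 90.9% of cells kept their class. Of the blood-like, gut endoderm-like and visceral or yolk-sac endoderm-like cells 100% did, of the endothelium-like 99.8%, of the amnion-like and mesenchyme-like 98.7% each and of the primordial germ cell-like 97.7%. Of the epiblast-like cells only 69.9% and of the trophoblast-like 68.8% did, and no nascent mesoderm-like class was found. The trophoblast-like class holds cluster 6, with a median of 6144 UMIs per cell and 0.258% mitochondrial UMIs, not far above the limit of 5000 for low-depth clusters, and the second seed gave 57119 low-depth and 17913 trophoblast-like cells.

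Several libraries of the same day were near-identical in composition. In 6 sets (E18 replicates 2 and 3, E19 replicates 2 and 3, E22 replicates 2 and 3, E23 replicates 2, 3 and 4, E24 replicates 2 and 3, E25 replicates 2 and 3) the chi-square per degree of freedom over the clusters was 0.935 to 2.57 in the 8 pairs, against 33 to 183 in the 18 other same-day pairs. Their gene counts still differed beyond counting error, with ratios to it of 2.92 to 14.7 against at least 57.0 in the other same-day pairs. The labels do not say whether libraries within a set came from separate embryos, and where they did not, the p-values over 24 libraries are too small. The totals of rising and falling genes and the called members of each list are therefore given with such libraries joined as well, which left 3 samples at E18 and 2 at every other day. Counts under another alternative are over libraries that were not joined.

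Blood-like cells were nearly absent before E23 and present in every sample from E23 on. They carried globin transcripts (HBE1, HBZ, HBA1, HBG2) and macrophage and neutrophil transcripts (C1QA, CSF1R, MPO). The 94 blood-like cells of E25 replicate 1 were an exception in type, with 1 count each of HBE1 and HBG2 and 9 of HBA1. Their mean share of cells was 0.00699% ± 0.0121 (SD, n = 3) at E18 and 0.0737% ± 0.00453 (SD, n = 2) at E22. It was 0.506% ± 0.0828 (SD, n = 2) at E23, 4.63% ± 5.25 (SD, n = 2) at E24 and 2.08% ± 1.07 (SD, n = 2) at E25. Each of the 6 samples from E23 to E25 (0.448% or more) lay above each of the 11 earlier samples (0.142% or less). None was found among 8119 cells of E20 replicate 1 or 9110 of E20 replicate 2, which allows shares of up to 0.0370% and 0.0329%. Over the 24 libraries Spearman's rho was 0.892, with a permutation p of 1e-05, the smallest that the resamples can give, and an adjusted p of 0.0001 over 10 classes. Pearson's r was 0.533 (permutation p = 0.00146) and 0.527 without the 2 libraries farthest from the median day. With the joined 17 samples rho was 0.853 (permutation p = 7e-05, adjusted p = 0.0007).

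The other 9 classes showed no trend with the day, all with an adjusted permutation p of 0.929. The rank correlation with the day was 0.132 for amnion-like, 0.0920 for trophoblast-like, 0.0520 for endothelium-like, -0.0190 for visceral or yolk-sac endoderm-like, -0.0290 for gut endoderm-like, -0.0810 for epiblast-like, -0.153 for nascent mesoderm-like, -0.187 for mesenchyme-like and -0.261 for primordial germ cell-like cells. Samples of a day differed widely: mesenchyme-like cells made up 24.7% ± 23 (SD, n = 2) at E21, and trophoblast-like cells 37% ± 32.4 (SD, n = 2) at E20 and 32.6% ± 2.79 (SD, n = 2) at E25. The missing trends do not show that shares were constant.

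**Figure D1:**
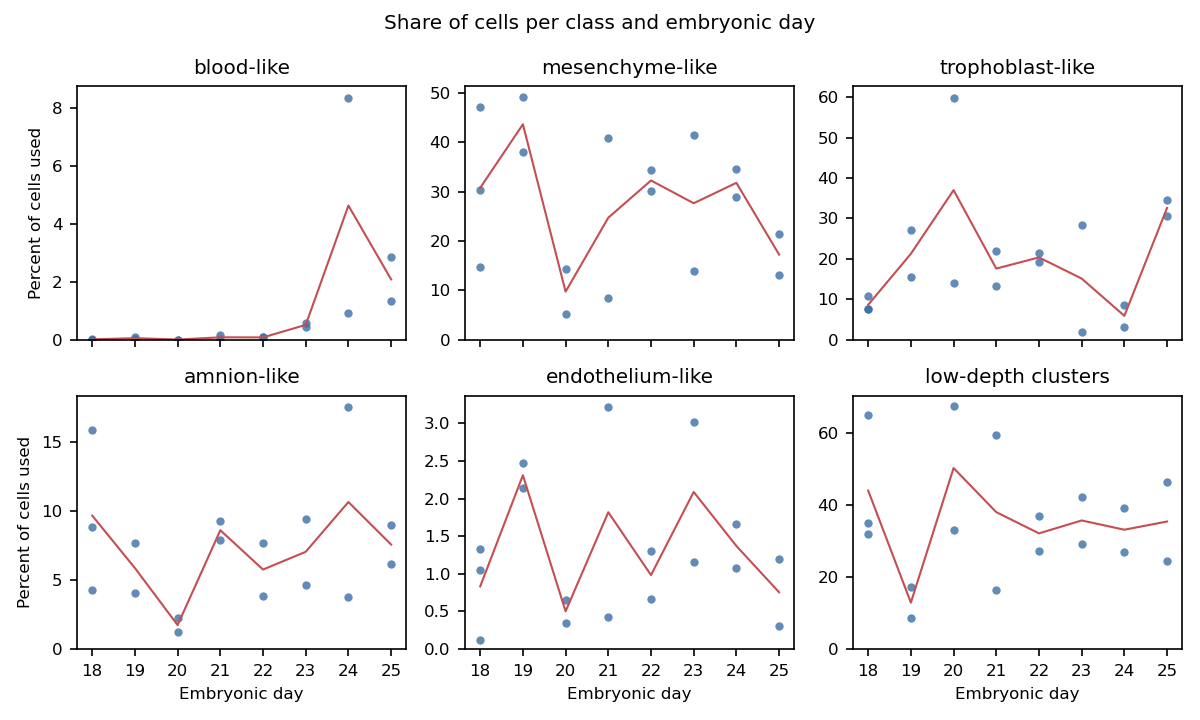
Percent of cells used (vertical axis) against embryonic day (horizontal axis) for 5 cell classes and the low-depth clusters; each point is a sample, near-identical libraries being averaged to 1 point, and the line joins the means of the days. Blood-like cells lie at 0.142% or less up to E22 and at 0.448% or more from E23.

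In whole libraries the steepest rises were in globins, the oxygen carriers of red cells, and the steepest falls in trophoblast hormones. HBE1 rose from 0.561 ± 0.314 CPM (SD, n = 3) at E18 to 1438 ± 2032 CPM (SD, n = 2) at E25, by 1.68 ± 0.236 (SE) log2 units per day, and HBZ (1.81), HBA1 (1.39) and HBG2 (1.22) rose with it. The share of blood-like cells rose over the same days. S100A9, a neutrophil protein, rose by 1.30 per day. CGB8, a chorionic gonadotropin subunit, fell from 194 ± 204 CPM (SD, n = 3) to 5.00 ± 1.85 CPM (SD, n = 2), with a slope of -0.69, and LEP (leptin) had a slope of -0.52. The other rising genes were AQP1 (0.37), CD44 (0.36), MFAP4 (0.26), BST2 (0.24), SST (0.21), COL9A3 (0.21) and KCTD12 (0.19). The other falling genes were SULT1C4 (-0.22), EGFL6 (-0.20), KRT8 (-0.16), C11H12orf75 (-0.16), ALYREF (-0.15), CDC20 (-0.14), KIF23 (-0.13), GLIPR2 (-0.13), UBE2C (-0.13) and RHOB (-0.13). With joined samples 6 of these 24 genes passed: HBZ, HBE1, HBA1, S100A9, HBG2 and KIF23 (adjusted p = 0.0195, 0.0109, 0.0134, 0.0498, 0.00676 and 0.0128).

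Of 20809 genes tested over the 24 libraries, 773 rose and 509 fell, and with joined samples 182 and 51 did, 211 of those 233 being among the former. Single libraries moved these counts by over 1.5 times: without E20 replicate 1, 805 genes fell, without E25 replicate 1, 977 fell, without E25 replicate 3, 316 fell, and without E24 replicate 2, 500 rose. The DESeq2 Wald test gave 1100 falling genes. None of the genes fixed in advance passed: the slope was -0.08 for TBXT (adjusted p = 0.854), -0.01 for SOX2 (0.964), -0.22 for POU5F1 (0.216), -0.13 for GATA4 (0.0593) and -0.12 for HAND1 (0.332). POU5F1, a pluripotency factor, was at 53.7 ± 25.8 CPM (SD, n = 3) at E18 and 7.92 ± 6.74 CPM (SD, n = 2) at E25, and HAND1, a mesoderm and trophoblast factor, at 862 ± 212 and 213 ± 148 CPM.

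The embryonic erythroid list rose in whole libraries (adjusted p = 0.00210, with joined samples 0.0476, adjusted p = 0.198 with an estimated correlation). Of its 17 genes tested 13 rose (9 with joined samples) and 14 did when adjusted over the list alone; HBM, an alpha-type globin, had a slope of 1.82 and HBA 1.36. Free RNA of blood-like cells as a source of globin transcripts was tested in trophoblast-like cells only, not in the other classes below. The mitosis (G2/M phase) list fell (adjusted p = 0.000703, joined 0.00677, adjusted p = 0.0856 with an estimated correlation), with 13 of 25 genes falling over libraries, 4 with joined samples, and 20 when adjusted over the list alone (19 joined). AURKA, a mitotic kinase, fell from 42.0 ± 6.27 CPM (SD, n = 3) to 24.1 ± 5.34 CPM (SD, n = 2) and BIRC5 (survivin) from 76.1 ± 17.5 to 34.4 ± 6.44 CPM. The DNA replication (S phase) list fell (adjusted p = 0.00210, joined 0.0248, adjusted p = 0.0856 with an estimated correlation), with 5 of 22 genes falling over libraries, 0 with joined samples, and 11 when adjusted over the list alone (9 joined). MCM6, part of the replicative helicase, fell from 58.0 ± 10.2 to 41.1 ± 0.570 CPM.

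The other 20 lists did not pass in whole libraries. Their adjusted p was 0.351 for the nuclear-encoded respiratory chain and the unfolded protein response, 0.557 for glycolysis and sterol synthesis, 0.616 for hepatic-type plasma proteins, 0.705 for sarcomere and cardiac and the retinoic acid pathway, 0.725 for hypoxia response and the NOTCH pathway and 0.736 for HOX paralogs 5 to 13. It was 0.770 for pluripotency, HOX paralogs 1 to 4, p53 targets, dissociation and immediate early, the BMP pathway and the FGF pathway, 0.790 for interferon response, 0.801 for primitive streak and nascent mesoderm, 0.839 for collagens and matrix and 0.954 for the WNT pathway. For HOX paralogs 1 to 4 the test pointed up and the median slope was -0.01. None of the 23 lists passed with camera in any fit, and every list called below is lost with its estimated correlation.

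In mesenchyme-like cells, MFAP4, COL11A1 and WNT2B rose, and over the 24 libraries the DNA replication list fell. MFAP4, a microfibril protein, rose from 43 ± 23.4 CPM (SD, n = 3) at E18 to 372 ± 167 CPM (SD, n = 2) at E25, and COL11A1, a fibrillar collagen, from 29.6 ± 17.8 to 95.5 ± 27.6 CPM. The transcription factor gene ZFHX4 (0.36 per day), the chaperone gene CLU (0.35), PAGE4 (0.31) and the guidance factor gene SLIT3 (0.27) rose, as did SST (0.25) and TCEAL2 (0.25). PAGE4 was among the 10 leading genes of trophoblast cluster 6, and RNA or cells of that class as its source were not tested for. SULT1C4, a sulfotransferase, fell from 338 ± 17.9 to 107 ± 1.5 CPM and SLC39A8, a zinc transporter, from 161 ± 75.4 to 53 ± 3.99 CPM. COCH (-0.43), ISM1 (-0.22), the epithelial keratin KRT8 (-0.22), C11H12orf75 (-0.21), EMP2 (-0.19) and SRPX2 (-0.18) also fell. With joined samples 9 of these 16 passed: the rising genes other than SST, SULT1C4 and SLC39A8 (adjusted p from 0.00409 for MFAP4 to 0.0460 for COL11A1).

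Of 17467 genes tested in mesenchyme-like cells, 1441 rose and 1191 fell, and with joined samples 303 and 131 did, 419 of these being among the former. With the second clustering seed 1369 rose and 1225 fell. Within the largest cluster of the class alone 488 rose and 556 fell. Over the pooled cells of a day, cluster make-up differed between days: cluster 0 held 33% of the mesenchyme-like cells at E23 and cluster 5 held 54.8% at E20. Cluster 0, with MFAP4, SST and ZFHX4 among its 10 leading genes, held 6.08% at E18 and 22.1% at E25. Cluster 13, with TCEAL2 among its leading genes, held 1.28% at E18 and 13.6% at E25. Cluster 12, with UHRF1 and GINS2 of the DNA replication list among its leading genes, held 13.3% at E18, 13.8% at E23 and 5.79% at E25. The class slopes of these genes and of the DNA replication list include any such shift between clusters. No list was tested within a cluster. Of the lists, 5 passed over 24 libraries and 0 with joined samples (fry), so the lists below passed over 24 libraries only. With joined samples the called members were 1 in DNA replication, 1 in pluripotency, 4 in embryonic erythroid, 2 in WNT pathway and 1 in NOTCH pathway. The DNA replication (S phase) list fell (12 of 22 genes, 16 when adjusted over the list alone, adjusted p = 0.00994), as did pluripotency (4 of 10, 4 alone with 1 rising, 0.0446). Embryonic erythroid (7 of 12, 7 alone, 0.0190), WNT pathway (3 of 17, 3 alone, 0.0190) and NOTCH pathway genes (2 of 14, 2 alone, 0.0379) rose, each at an adjusted p = 0.522 with an estimated correlation, as for the falling lists. WNT2B, a WNT ligand, rose by 0.74 per day from 0.143 ± 0.155 to 3.75 ± 0.312 CPM (joined adjusted p = 0.000585), WNT5B by 0.27 (0.0265) and the NOTCH ligand gene DLL1 by 0.22 (0.0344). TCF7 of the WNT list fell by 0.11. HBZ, HBE1, HBG2 and HBA1 rose by 1.83, 0.97, 0.45 and 0.92 per day, while blood-like cells became more frequent.

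In trophoblast-like cells, the gonadotropin gene CGB8 and the mitosis and DNA replication lists fell, while the NOTCH pathway list rose. CGB8 fell from 848 ± 689 CPM (SD, n = 3) at E18 to 9.19 ± 2.04 CPM (SD, n = 2) at E25, and LEP had a slope of -0.56. HPGD, which degrades prostaglandins, rose from 212 ± 78.3 to 1191 ± 799 CPM. GAST (0.57 per day), MAMU-A, a major histocompatibility gene (0.42), ANKRD37 (0.39), the defensin gene DEFB1 (0.35), CST6 (0.34), INHBA, an activin subunit (0.32), and MFGE8 (0.31) rose. ODC1, of polyamine synthesis (-0.33), RARRES1 (-0.32), CDH5 (-0.28), ACVRL1 (-0.27), DUSP5 (-0.25) and SUMO2 (-0.23) fell. CDH5 is a marker by which endothelium clusters were named, and whether it came from the trophoblast-like cells themselves was not tested. With joined samples only CGB8, ODC1 and DUSP5 of these 16 passed (adjusted p = 0.0253, 0.0236 and 0.0294).

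The NOTCH pathway list (6 of 12 genes rose and 1 fell, 6 and 1 when adjusted over the list alone, adjusted p = 0.000967), the mitosis (G2/M phase) list (19 of 25 fell, 24 alone, 0.000156) and the DNA replication (S phase) list (12 of 22 fell, 15 alone, 0.000967) also passed with joined samples (0.0359, 0.0120 and 0.0359), with an adjusted p = 0.141 each with an estimated correlation. Of their genes only 1, 2 and 0 passed with joined samples (6 rising and 1 falling, 21 and 8 when adjusted over the list alone). NOTCH3, a receptor, rose from 2.73 ± 0.404 CPM (SD, n = 3) to 9.40 ± 1.42 CPM (SD, n = 2), and HES1, a NOTCH target, from 17 ± 6.48 to 42.3 ± 19.9 CPM. The gene that fell was DLL3, a ligand gene (-0.24). BIRC5 (survivin) fell from 60.1 ± 5.90 to 23.1 ± 0.729 CPM and PLK1 by 0.16 per day. The other 5 lists passed over 24 libraries only, and with joined samples their called members were 1 in collagens and matrix, 3 in embryonic erythroid and 0 in each of the others. Collagens and matrix (5 of 24, 15 alone, adjusted p = 0.0382) rose, with the basement membrane collagens COL4A1 (from 63.2 ± 9.19 to 297 ± 22.2 CPM) and COL4A2 (0.17) and with SPARC (0.16, joined adjusted p = 0.0438). The list holds collagens by which mesenchyme clusters were named, and RNA or cells of that class as the source were not tested for. Hypoxia response (4 of 18, 7 alone, 0.0440), p53 targets (2 of 17, 2 alone, 0.0382), the retinoic acid pathway (1 of 7, the gene DHRS3 at 0.29, 2 alone, 0.0382) and embryonic erythroid genes (3 of 8, 3 alone, 0.0183) rose. For these 5 the adjusted p with an estimated correlation was 0.372. The list of hepatic-type plasma proteins, which include markers of visceral or yolk-sac endoderm, did not pass in any class. Yet 8 of its 13 genes rose here over libraries (adjusted p of the list 0.144, 0 genes with joined samples), 6 of 15 in mesenchyme-like cells (0.0997, 1 joined) and 3 of 11 in amnion-like cells (0.246, 0 joined), and RNA or cells of another class as their source were not tested for. HBE1 rose by 1.45 per day, HBG2 by 1.06 and HBA1 by 0.83, while blood-like cells became more frequent.

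Of 14652 genes tested in trophoblast-like cells, 808 rose and 908 fell, and with joined samples 47 and 43 did, 87 of these being among the former. With the second clustering seed, which placed fewer cells in the class, 1039 rose and 1027 fell, and 1570 of these were among the former. Without E25 replicate 2, 425 rose and 460 fell, without E25 replicate 3, 439 and 459 did, and 572 fell without E18 replicate 1 and 568 without E24 replicate 2. Within the largest cluster of the class 53 rose and 41 fell. Over the pooled cells of a day, cluster make-up differed between days. Cluster 24 held 50.9% of the class at E19 and cluster 32 held 24.6% at E25. The shallow cluster 6 held 40% at E18, 7.43% at E19 and 59.5% at E21. Of the barcodes of cluster 32, 90.3% came from E25 replicate 1, so its share at E25 is mostly that of 1 library. Cluster 14, with HPGD and INHBA among its 10 leading genes, held 10.0% at E18, 6.61% at E23 and 23.2% at E25. Cluster 1, the largest of the class, held 32.0% at E18, 41.1% at E24 and 10.0% at E25. The class slopes of HPGD and INHBA and of the mitosis, DNA replication and NOTCH lists include any such shift between clusters. The lists were not tested within a cluster. The difference in slope between trophoblast-like and mesenchyme-like cells was tested over the joined samples. Of 20440 genes 3 had a more positive slope in trophoblast-like cells (PARVG, SPTSSA and RRAGC, named after their values were seen) and 7 in mesenchyme-like cells. Which of the 2 slopes was the steeper does not follow from these counts. For 0 of the 23 lists did the slope differ (fry, smallest adjusted p = 0.810 and smallest unadjusted p = 0.0573, for p53 targets).

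In endothelium-like cells, the lists of DNA replication and mitosis fell and genes such as STAB2, AQP1 and DLK1 rose. All 20 DNA replication (S phase) genes tested fell (20 when adjusted over the list alone, 15 with joined samples, adjusted p = 0.00178, joined 0.0165), and 22 of 25 mitosis (G2/M phase) genes did (25 alone, 15 with joined samples, 0.00287, joined 0.0165). RRM2, a subunit of ribonucleotide reductase, fell from 103 ± 52.1 CPM (SD, n = 2) at E18 to 9.63 ± 13.6 CPM (SD, n = 2) at E25 and CDK1, the mitotic kinase, from 124 ± 37.3 to 19 ± 15.7 CPM. STAB2, a scavenger receptor of sinusoids, rose from 108 ± 73.5 to 337 ± 193 CPM, with SELENOP (0.42 per day), DLK1 (0.39), the water channel AQP1 (0.86), FCGR2B (0.46), TTR, a marker of visceral or yolk-sac endoderm (0.62), and NFIB (0.33). HBA1 had a slope of 1.06, from 2.81 ± 0.515 to 15.1 ± 21.4 CPM, while blood-like cells became more frequent and its whole-library level went from 0.491 ± 0.232 CPM (SD, n = 3) to 595 ± 839 CPM (SD, n = 2). At E25 the SD exceeded the mean for both RRM2 and HBA1. The 2 samples of that day had endothelium-like shares of 0.309% and 1.20%, so 1 of them held few such cells. ETV2, a factor that starts the endothelial program, had a slope of -0.40, TGFBI -0.39, CKB -0.34, UBE2C -0.34, BMP2 -0.34, CDH11 -0.33 and GLIPR2 -0.32. With joined samples 9 of these 16 passed: HBA1, AQP1, SELENOP, STAB2, DLK1, RRM2, UBE2C, BMP2 and GLIPR2, with adjusted p from 0.0161 to 0.0367.

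Of 10823 genes tested in endothelium-like cells (22 libraries, 16 joined samples), 666 rose and 1176 fell, and with joined samples 244 and 389 did, 614 of these being among the former. With the second clustering seed 664 rose and 1177 fell. Without E18 replicate 1, 420 rose and 755 fell, and with at least 50 cells per library 1100 rose. The other 6 lists also passed with joined samples, but few of their genes did: 2 in the respiratory chain, 2 in the unfolded protein response, 1 in sterol synthesis, 1 in pluripotency and 0 in both HOX paralogs 1 to 4 and hypoxia response. Over libraries, the nuclear-encoded respiratory chain (9 of 34, 9 alone, adjusted p = 0.00316, joined 0.0443), the unfolded protein response (7 of 15, 7 alone, 0.00217, joined 0.0304), sterol synthesis (5 of 16, 8 alone, 0.00699, joined 0.0304) and pluripotency (1 of 6, the gene ZFP42 at -0.23, 2 alone, 0.0220, joined 0.0357) fell. HOX paralogs 1 to 4 (2 of 4, 2 alone, 0.00178, joined 0.0165) and hypoxia response (2 of 17, 2 alone, 0.00699, joined 0.0304) rose; HOXB3 had a slope of 0.16, HOXB4 of 0.14, DDIT4 of 0.23 and NDRG1 of 0.24. With an estimated correlation the adjusted p was 0.436 for pluripotency and 0.335 for the other 7 lists.

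In amnion-like cells, the sterol synthesis list, CTHRC1 and CADM1 fell. The sterol synthesis list fell (3 of 16 genes, 1 with joined samples, 8 when adjusted over the list alone, adjusted p = 0.00100, joined 0.00913, adjusted p = 0.182 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 125 ± 17.5 CPM (SD, n = 3) to 53.2 ± 0.797 CPM (SD, n = 2), and MSMO1 from 150 ± 20.6 to 67.0 ± 0.558 CPM. CTHRC1, a secreted matrix-linked protein, fell from 2119 ± 657 to 486 ± 34.3 CPM and the adhesion gene CADM1 from 230 ± 76.5 to 80 ± 29.5 CPM, and these were the only 2 of the 16 named genes to pass with joined samples (adjusted p = 0.0141 and 0.0426). LUM (-0.46 per day), FN1 (-0.30), NTS (-0.24), CST3 (-0.23), IGFBP7 (-0.22) and WNT5A (-0.21) fell, of which LUM is a marker by which mesenchyme clusters were named, with its source not tested. SERPINF1 (0.33), AQP1 (0.25), FXYD3 (0.22), IQGAP2 (0.18), RARRES2 (0.17), DPRX (0.14), EPO (0.13) and NACA2 (0.12) rose over 24 libraries. FXYD3 was a leading gene of trophoblast cluster 32 and AQP1 of the unnamed cluster 11, and RNA or cells of these clusters as the source were not tested for. Over the pooled cells of a day, cluster make-up differed at E25. Cluster 41 had LCN2 among its leading genes and 31.5% of its barcodes marked by Scrublet (these were removed). It held 28.3% of the class at E25 and 7.20% or less on each other day. Of its barcodes 40.4% came from E25 replicate 1. Cluster 4 held 72.3% at E18 and 52.9% at E25.

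In amnion-like cells over 24 libraries the embryonic erythroid list (2 of 9 rose, 3 alone), the unfolded protein response list (5 of 16 fell, 6 alone) and the HOX paralogs 5 to 13 list (0 of 20 called, 6 falling alone) passed the list test, the first upward and the others downward (adjusted p = 0.0421 each, adjusted p = 0.427 each with an estimated correlation), and none of these 3 passed with joined samples (0.167 each; 1, 0 and 0 genes called). Of 14686 genes tested, 180 rose and 257 fell, and with joined samples 3 and 10 did, 12 of these being among the former. The 3 rising genes, named after their values were seen, were HBA1, HBE1 and LOC107000097, with 2 globins among them while blood-like cells became more frequent. HBA1 was at 0.0598 ± 0.104 CPM (SD, n = 3) at E18 and 12 ± 16.6 CPM (SD, n = 2) at E25. With the second clustering seed 166 rose and 239 fell. The amnion counts rested on single libraries. Without E18 replicates 2 or 4 the rising genes were 111 and 90, and without E25 replicates 2 and 3, 106 and 99. The falling genes were 137 without E18 replicate 4 and 414, 168 and 158 without E25 replicates 1, 2 and 3. The DESeq2 Wald test gave 328 and 491, no filter on low counts 279 rising, and E18 and E19 against E24 and E25 gave 43 and 57.

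In gut endoderm-like cells, FXYD3, S100P and SERPINA1 rose, and over the 18 libraries with enough cells the lists of glycolysis and the unfolded protein response fell. FXYD3 rose from 0.759 ± 0.126 CPM (SD, n = 2) at E18 to 74 CPM (n = 1) at E25 and S100P from 9.13 ± 2.69 to 726 CPM, the E25 values resting on 23 cells of E25 replicate 1, with SERPINA1 (0.98 per day), DEFB1 (1.07), ANXA1 (0.83), UPK3A (0.80), PAG1 (0.71) and RARRES2 (0.70). SPP1 (-0.97), NPY (-0.59), ALAS2 (-0.53), CFC1, a NODAL co-receptor (-0.45), LRP2 (-0.44), VEPH1 (-0.43), RSPO3 (-0.41) and TMEM88 (-0.39) fell. FXYD3 was a leading gene of trophoblast cluster 32, with 90.3% of its barcodes from E25 replicate 1, and S100P of the trophoblast-type low-depth cluster 7. SERPINA1 is a marker by which visceral or yolk-sac endoderm clusters were named, ANXA1 one of mesenchyme and ALAS2 one of erythroid cells, and RNA or cells of other classes as the source of these 5 genes were not tested for. With joined samples only FXYD3, SERPINA1 and S100P of the 16 passed (adjusted p = 0.0200, 0.0462 and 0.0382). Glycolysis (11 of 17, 12 alone, adjusted p = 0.0104) and unfolded protein response genes (6 of 13, 6 alone, 0.0350) fell over the libraries, with joined values of 0.102 and 0.240, 2 and 0 genes falling with joined samples, and an adjusted p = 0.75 each with an estimated correlation. In glycolysis 1 gene, the hexokinase gene HK1, rose (0.12), and GAPDH fell from 3698 ± 558 to 1714 CPM (joined adjusted p = 0.0435). Of 11568 genes tested in 18 libraries, 986 rose and 679 fell, and in 12 joined samples 124 and 33 did, 149 of these being among the former. With the second clustering seed 962 rose and 683 fell. Without E24 replicate 2, 438 fell, and without E24 replicate 3, 448. With at least 50 cells the counts were 378 and 193, for E18 and E19 against E24 and E25 398 and 150, and at Leiden resolution 2, which drew the class differently, 29 and 23. There the class was cluster 50, with 1163 barcodes against 2162 at resolution 1. The unnamed cluster 56, with 996 barcodes and primitive streak as its best list, had IHH, TNNC1, COL9A2 and FOXA2 among its leading genes. These 4 also led the class at resolution 1. Whether a shift between such cells moved the class slopes was not tested.

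Epiblast-like, primordial germ cell-like and visceral or yolk-sac endoderm-like cells had few or no trends that held with joined samples. Visceral or yolk-sac endoderm-like cells had rising slopes over 13 libraries for the liver-type secreted proteins AFP (0.43), APOA2 (0.51), AHSG (0.44) and APOH (0.42), for CIDEB (0.48), SLC47A1 (0.42), PTPRD (0.39) and SLC17A3 (0.38), and falling slopes for PMEL (-0.34), CPVL (-0.33), ASS1 (-0.31), ATP1B1 (-0.29), RGS5 (-0.28), KRT8 (-0.23), EBPL (-0.23) and PXDN (-0.21). RGS5 is on the marker list of smooth muscle or pericytes. None of these 16 passed in the 8 joined samples. APOA2 was at 213 CPM at E18 and 4423 CPM at E25 (n = 1 each). Here 131 genes rose and 62 fell over libraries and 0 did with joined samples in edgeR, with 1112 at an unadjusted p under 0.05. The DESeq2 Wald test over libraries gave 315 and 275. Omission of a single library gave 22 to 188 rising and 12 to 114 falling genes. The counts were 39 and 32 without E19 replicate 2, 63 and 35 without E19 replicate 3, 68 and 38 without E21 replicate 1, 84 and 40 without E22 replicate 3, and 57 and 22, 37 and 16, and 49 and 19 without E23 replicates 2, 3 and 4. They were 188 and 114 without E24 replicate 1, 28 and 13 and 22 and 12 without E25 replicates 2 and 3, and 104 falling without E18 replicate 2. The embryonic erythroid list rose over libraries, while blood-like cells became more frequent (2 of 7, 3 alone, 0 with joined samples, adjusted p = 0.0177, joined 0.339, adjusted p = 0.626 with an estimated correlation).

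In epiblast-like cells COL1A2 and POSTN rose and DPPA5, KHDC3L and PLPP2 fell over 21 libraries, and of these only PLPP2 passed in the 14 joined samples. Among 12624 genes 34 rose and 44 fell; joined, 1 rose and 1 fell, HBG2 (0.82 in joined samples, 0.84 over libraries) and PLPP2 (-0.24, joined adjusted p = 0.0213), and HBG2 was named after its value was seen, while blood-like cells became more frequent. COL1A2 rose by 0.59 per day, from 74.7 ± 28.2 CPM (SD, n = 3) at E18 to 3932 ± 4881 CPM (SD, n = 2) at E25, with POSTN (0.57), COL5A2 (0.54), COL1A1 (0.45), COL5A1 (0.39), SAT1 (0.15) and TAF1D (0.10). KHDC3L (-0.88), DPPA5 (-0.63), KRT8 (-0.35), TRIML2 (-0.33), ASS1 (-0.21), CRABP2 (-0.20) and CMBL (-0.17) fell. COL1A1, COL1A2 and POSTN are markers by which mesenchyme clusters were named, and mesenchyme-like cells or their RNA among the epiblast-like cells were not tested for as the source. The collagens and matrix list did not pass here (adjusted p = 0.0755, joined 0.264). Cluster make-up over the pooled cells of a day differed too. Cluster 45, led by LCN2, PMAIP1 and DDIT3, held 4.50% of the class at E18 and 43.6% at E25. At E21, a day with too few cells to enter the fit, it had 16 cells against 8 in the other cluster. Cluster 28, led by PTPRZ1 and SOX2, held the rest. E25 replicate 1 gave 27.8% of the barcodes of cluster 45, more than any other library. Cluster 45 had a median of 0.0529% mitochondrial UMIs against 3.66% in cluster 28, and no epiblast marker among its 10 leading genes. With the second clustering seed 31 rose and 15 fell, and only 16 of these were among the 78.

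The embryonic erythroid list rose in epiblast-like cells (2 of 5, 1 with joined samples, 3 alone, adjusted p = 0.00101, joined 0.0213, adjusted p = 0.0686 with an estimated correlation) and the glycolysis list passed downward with no gene called (0 of 18, 0 with joined samples, 6 falling and 1 rising alone, 0.0216, joined 0.151, adjusted p = 0.136 with an estimated correlation). The counts of rising and falling genes moved with single libraries: 53 and 113 without E18 replicate 1, 14 and 20 without E18 replicate 2, 5 and 5 without E18 replicate 3, 17 and 28 without E19 replicate 1, and 61 and 67 without E20 replicate 2. They were 53 rising without E24 replicate 1, 29 and 27 falling without E23 replicates 3 and 4, 18 and 27 without E24 replicate 2, 14 and 21 without E24 replicate 3, 81 falling without E25 replicate 1, and 12 and 20 and 20 and 20 without E25 replicates 2 and 3. The DESeq2 Wald test over libraries gave 103 and 168.

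In primordial germ cell-like cells only 2 genes rose and 0 fell over 16 libraries: NACA2 (0.15) and PARVB (0.33), the latter named after its value was seen. With joined samples 0 did in edgeR, with 596 at an unadjusted p under 0.05, and the DESeq2 Wald test over libraries gave 31 and 16. No list passed in this class. No gene rose without E18 replicate 2 or 3, E19 replicate 2, E23 replicate 2, 3 or 4, E24 replicate 1 or 2, or E25 replicate 1, and 1 rose without E19 replicate 1 or 3. Without E18 replicate 1, 4 fell, and 1 did without E18 replicate 4, E20 replicate 2, E21 replicate 1 or E22 replicate 1, or with the second clustering seed.

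**Figure D2:**
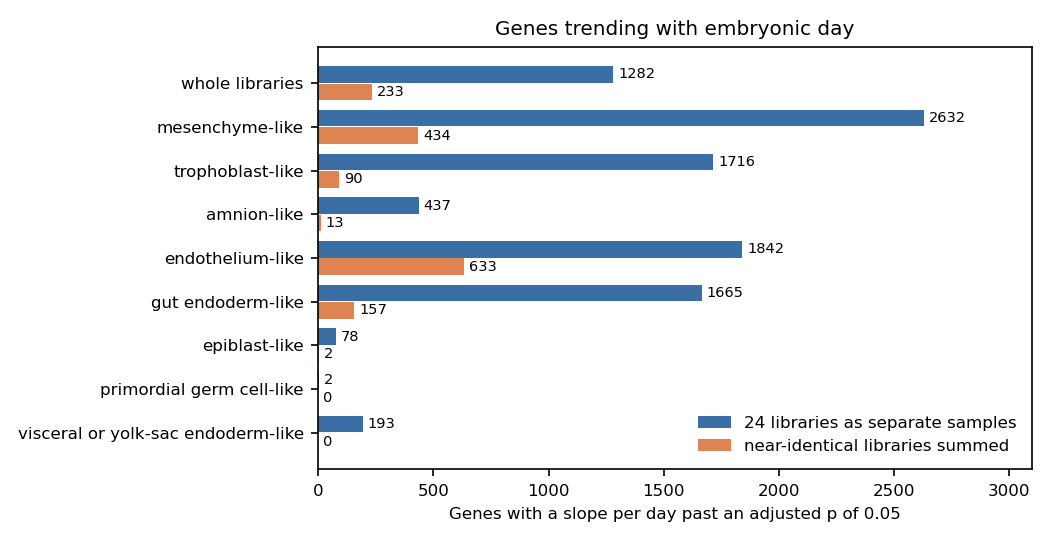
Number of genes past an adjusted p of 0.05 for a slope per embryonic day (horizontal axis, starting at 0) in whole libraries and 8 classes, with the 24 libraries as separate samples (blue) and with near-identical libraries summed (orange). Joining lowered the count everywhere, from 1282 to 233 in whole libraries and from 2632 to 434 in mesenchyme-like cells.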

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

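Tests on the near-identical libraries, the depth test in mesenchyme-like cells and the splits of single and of summed libraries were chosen after the results were seen; the tests of hemoglobin ratios and of the largest mesenchyme cluster and the splits with near-identical libraries dealt together were written down before. Shares of cells at E18 and E23, the days with 4 libraries, were checked for a library far from the others. Of 24 shares 11 stood apart. The libraries of a day are not all separate here, since E18 replicates 2 and 3 and E23 replicates 2, 3 and 4 are near-identical sets, and a library outside a set stands apart from it readily, so the 11 cannot be set against a chance rate.

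At E23, 8 shares of replicate 1 stood apart from those of the other 3 libraries, which are a near-identical set, so these values amount to 1 difference between 2 samples. Trophoblast-like cells were 28.3% of cells in E23 replicate 1 (95% interval 27.2 to 29.4) against 1.79% to 2.11% in the others and mesenchyme-like cells 13.9% (13.1 to 14.7) against 40.8% to 42.7%. Its amnion-like share was 4.64% (4.16 to 5.18) against 9.21% or more, its endothelium-like share 1.16% (0.928 to 1.45) against 2.84% or more, its gut endoderm-like share 0.626% (0.462 to 0.848) against 2.62% or more, and its primordial germ cell-like share 0.244% (0.150 to 0.397) against 1.20% or more. Visceral or yolk-sac endoderm-like cells were 0.275% (0.174 to 0.434) against 1.52% or more. Nascent mesoderm-like cells were 0 of 6549, which allows a share of up to 0.0458%, against 1.52% or more.

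At E18, replicate 4 had 64.9% of its cells in low-depth clusters (63.6 to 66.3) against 31.9% to 37.6% in the others. E18 replicate 1 had 3.61% nascent mesoderm-like cells (3.19 to 4.1) against 0.303% or less. In E18 replicate 2 the blood-like share of 0.0419% (0.00740 to 0.237) was 1 cell of 2386, where the others had none, so that its standing apart follows from the counting of a single cell.

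Pattern of near-identical libraries. The same library deposited more than once is excluded, since joined pairs shared at most 0.445% of the barcodes of the smaller library. A candidate explanation is that 1 pool of cells was loaded more than once: in 6 of 6 sets all libraries held Y-linked transcripts (DDX3Y, EIF1AY, RPS4Y1) or none did, while 10 of the 18 other same-day pairs differed. Libraries with them had 1151 to 1481 CPM and those without at most 0.0435 CPM. Embryos of 1 sex that developed alike would also match, and no biological explanation was tested. Under a single pool the 17 joined samples, not the 24 libraries, would be the replicates.

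Pattern of hemoglobin transcripts rising in trophoblast-like cells. If free RNA from the captured blood-like cells were the cause, HBE1, HBG2 and HBA1 would keep the ratios of those cells. The median absolute difference of the log2 ratios between the 2 classes was 1.36 (quartiles 0.844 and 1.61) over 28 ratios in 10 libraries, and 1.36 over the 18 ratios with at least 20 counts, with HBA1 relatively higher in trophoblast-like cells in 16 of 19. Free RNA of the captured blood-like cells as the whole cause is thus argued against, and as part of the cause it stays open. HBE1 to HBG2 differed by -0.591 and -0.439 in E25 replicates 2 and 3, and by -1.13 and -1.55 in E24 replicates 2 and 3. The ratios of a library are not independent, and near-identical libraries are among the 10. Some ratios rest on few counts, as in E25 replicate 1, with 1 count each of HBE1 and HBG2 in blood-like cells. Free RNA of red cells that were not captured, and transcription in the trophoblast-like cells, stay open.

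Pattern of genes trending in mesenchyme-like cells. Differences in depth between whole libraries as the cause are argued against, since 96.9% of the called genes remained called with the depth covariate over the 24 libraries. That covariate was the median UMIs per cell over all cells used of a library. It takes in low-depth clusters, so depth within the mesenchyme-like cells was not tested. A shift between clusters of the class as the whole cause is argued against, but narrowly: in the largest cluster the median slope was 0.774 of that in the class (quartiles 0.514 and 1.02) over 1994 genes, 96.5% with the same sign. That lies just over the bound set beforehand, and an earlier run of the same scripts with other thread settings lay just under it. The largest cluster is itself part of the class sums, and the median does not speak for single genes. The embryonic day itself, which the design names, stays open.

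For whole libraries, 1 of 22 splits was as large when each library was dealt a day by itself (real count 1282, highest other 0). These splits broke up the near-identical sets, so they cannot exclude chance. With near-identical libraries summed, chance is argued against (1 of 22, 233 against 0), at the smallest share that 22 splits can give. With near-identical libraries dealt a day together under the 24-library test, chance is not excluded: 5 of 22 splits gave as many genes, up to 2411. That points to the structure of near-identical sets. The 1282 calls are therefore not to be read without the joined count.

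For classes, splits of single libraries gave the real count as the largest (1 of 22 each) in every class but primordial germ cell-like (2 of 22, real count 2, highest other 4). These splits too broke up the near-identical sets, so they cannot exclude chance. The real count and the highest other were 2632 and 0 in mesenchyme-like, 1716 and 1 in trophoblast-like, 437 and 0 in amnion-like, 1842 and 0 in endothelium-like, 1665 and 2 in gut endoderm-like, 78 and 0 in epiblast-like and 193 and 1 in visceral or yolk-sac endoderm-like cells. With near-identical libraries summed chance is argued against (1 of 22 splits, the smallest share possible) in mesenchyme-like (434 against 1), trophoblast-like (90 against 0), amnion-like (13 against 0), endothelium-like (633 against 1) and gut endoderm-like cells (157 against 3). In epiblast-like cells the 2 called genes stood against 0 in every other split, too few genes to exclude chance by, since the splits dealt together do not exclude it. In the primordial germ cell-like and visceral or yolk-sac endoderm-like classes no gene was called (edgeR) and all 22 splits gave as many, with at most 1 and 0. With near-identical libraries dealt together, the real count was the largest (1 of 22 splits) in mesenchyme-like (highest other 656), trophoblast-like (241), amnion-like (298), endothelium-like (544), gut endoderm-like (478) and visceral or yolk-sac endoderm-like cells (134). This argues against chance in these classes, except in visceral or yolk-sac endoderm-like cells, where no gene was called with libraries summed. Chance is not excluded in epiblast-like (2 of 22, up to 91) and primordial germ cell-like cells (3 of 22, up to 37). Counts this high in other splits point to the same structure.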

How the results depend on the processing

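Joined libraries, the second clustering seed, the adequate-depth cells, the omission of libraries mostly in low-depth clusters and the largest cluster of a class were chosen after the data were seen; the other alternatives were fixed beforehand. The rise of the blood-like share kept its direction and passed under every alternative, with rho from 0.822 with the replicate block to 0.918. The replicate block carries no pairing: of 72 same-number pairs of libraries 40 correlated at or under 0.1, and 11 of 24 libraries correlated best with their own number. Over the named genes 3963 values kept direction and side of the threshold, 867 were weaker, 9 stronger and 6 reversed. In gut endoderm these were LRP2 (0.15 at Leiden resolution 2) and RSPO3 (0.01 with at least 50 cells), and the other 4 were of SOX2 in whole libraries: 0.05 with the replicate block, 0.01 with the depth covariate, 0.08 without libraries mostly in low-depth clusters and 0.11 without E18 replicate 4 (with single libraries left out it lay between -0.03 and 0.11). DESeq2 size factors moved no count by over 1.5 times. Where a count fell because fewer samples or cells entered, the alternative's construction gives the cause; for all others the cause was not tested.

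With near-identical libraries summed the rising and falling genes were 182 and 51 in whole libraries, 303 and 131 in mesenchyme, 47 and 43 in trophoblast, 3 and 10 in amnion, 244 and 389 in endothelium, 124 and 33 in gut endoderm, 1 and 1 in epiblast, and 0 and 0 in primordial germ cell and visceral or yolk-sac endoderm (edgeR, with 596 and 1112 at an unadjusted p under 0.05). The lists past the threshold became 0 in mesenchyme, 3 in trophoblast, 1 in amnion, 0 in gut endoderm, 1 in epiblast and 0 in visceral or yolk-sac endoderm. With camera and an estimated correlation 0 lists passed in any fit, where fry called 3, 5, 8, 4, 8, 2, 2, 0 and 1 in the order of the fits.

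The clustering was repeated with a second seed after a first full run, made with other thread settings, had given other clusters. This was put down to small rounding differences in the principal components, which was not tested. All values given are of the run with a single thread, which repeats exactly. The second seed gave 1369 and 1225 in mesenchyme, 1039 and 1027 in trophoblast, 166 and 239 in amnion, 664 and 1177 in endothelium, 962 and 683 in gut endoderm, 31 and 15 in epiblast, 2 and 1 in primordial germ cell and 131 and 62 in visceral or yolk-sac endoderm. It left the blood-like rho at 0.892 and found no nascent mesoderm class.

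The DESeq2 Wald test gave 1100 falling genes in whole libraries, 328 rising and 491 falling in amnion, 103 and 168 in epiblast, 31 and 16 in primordial germ cell and 315 and 275 in visceral or yolk-sac endoderm. Without a filter on low counts it was 279 rising in amnion, 74 and 67 in epiblast and 25 and 8 in primordial germ cell. E18 and E19 against E24 and E25 gave 43 and 57 in amnion, 398 and 150 in gut endoderm, 3 and 2 in epiblast, 0 rising in primordial germ cell and 2 and 0 in visceral or yolk-sac endoderm. At least 50 cells per library gave 1100 rising in endothelium, 378 and 193 in gut endoderm, 17 and 17 in epiblast, 4 and 5 in primordial germ cell and 100 falling in visceral or yolk-sac endoderm. Leiden resolution 2 gave 29 and 23 in gut endoderm and 3 and 15 in epiblast. The largest cluster alone gave 488 and 556 in mesenchyme and 53 and 41 in trophoblast.

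The replicate block gave 41 and 16 in visceral or yolk-sac endoderm, 0 rising in primordial germ cell and 1 list in gut endoderm. The depth covariate gave 9 lists in mesenchyme, 1 in amnion and 4 in gut endoderm, 52 rising in epiblast, 5 and 3 in primordial germ cell, and 22 and 13 and 0 lists in visceral or yolk-sac endoderm. With Scrublet-marked barcodes kept epiblast had 18 rising, primordial germ cell 0 rising and visceral or yolk-sac endoderm 60 and 37, with the stricter cell filter primordial germ cell had 1 rising and visceral or yolk-sac endoderm 26 and 14, and without libraries mostly in low-depth clusters primordial germ cell had 2 falling.

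Shares without a trend changed sign as follows, none past the threshold. The rank correlation with the day for endothelium was -0.182 with the replicate block, -0.148 without libraries mostly in low-depth clusters, -0.164 without E18 and -0.0210 as a percent of cells outside the largest class. That for epiblast was 0.00900 without E18 and 0.0170 with the second clustering seed, for trophoblast -0.0490 without E18 and -0.0120 outside the largest class, for gut endoderm 0.370 at Leiden resolution 2 and 0.0290 with Scrublet-marked barcodes kept, and for visceral or yolk-sac endoderm 0.0320 with near-identical libraries averaged.

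Leaving out each library in turn gave, for rising and falling genes, 500 to 856 and 316 to 977 in whole libraries, 1097 to 1536 and 795 to 1392 in mesenchyme, 425 to 1089 and 459 to 1120 in trophoblast, 90 to 235 and 137 to 414 in amnion, 420 to 795 and 755 to 1286 in endothelium, 661 to 1094 and 438 to 909 in gut endoderm, 5 to 61 and 5 to 113 in epiblast, 0 to 3 and 0 to 4 in primordial germ cell, and 22 to 188 and 12 to 114 in visceral or yolk-sac endoderm. The rank correlation of the share ranged from -0.0630 to 0.165 for endothelium, -0.118 to 0.0730 for gut endoderm, -0.0160 to 0.163 for trophoblast and -0.106 to 0.0810 for visceral or yolk-sac endoderm. In simulated whole libraries that were independent of each other 55% of 2-fold changes were recovered, so absent calls do not show absent change; no such rate was simulated for the near-identical sets or for the classes.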

Other observations

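The 4577 cells of cluster 11 stayed unnamed because, although 12 mesenchyme markers supported it, its 10 leading genes held 0 of these and 1 marker of another list. It was led by SLC5A12, AGTR1, CD44, STMN2 and AQP1, beside mesenchyme markers such as POSTN and COL1A1. Its mean share of cells was 0.466% ± 0.690 (SD, n = 3) at E18, 4.38% ± 1.89 (SD, n = 2) at E19, 0.0308% ± 0.0436 (SD, n = 2) at E20, 2.62% ± 3.71 (SD, n = 2) at E21, 1.57% ± 0.640 (SD, n = 2) at E22, 6.08% ± 0.857 (SD, n = 2) at E23, 5.55% ± 4.58 (SD, n = 2) at E24 and 2.29% ± 3 (SD, n = 2) at E25. AQP1 and CD44, which rose in whole libraries, were among its leading genes. No trend was tested for it.

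Epiblast-like cells were of 2 clusters. Cluster 28, led by PTPRZ1, SOX2, DPPA5 and DNMT3B, held 95.5% of them at E18 and 87.9% at E24. Cluster 45, led by LCN2, ID4, TAC1, PMAIP1 and DDIT3, some of them genes of stress and cell death, held 43.6% at E25, and at E21 it had 16 cells and cluster 28 had 8. Y-linked transcripts were found in 11 of the 24 libraries and in 7 of the 17 joined samples; sex is not labelled and was not used in any test.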
